A study of Mus musculus with 4 samples.

How the data were processed

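Gene expression was measured in single nuclei of the mouse lateral septum by 10x Multiome, in 2 libraries of trained and 2 of naive female mice in proestrus. Per the labels' protocols, punches of 1.25 mm from sections of 1 mm were pooled by group, nuclei were stained and sorted as singlets, and conditioning had a baseline of 240 s and intervals of 100 s between trials. Per the submitters' processing notes, reads were processed with Cell Ranger ARC 7.0.0, and Seurat 5.2.1 was also used, on the mouse build mm10; the file headers name another Cell Ranger ARC version. The authors then kept 24912 nuclei by criteria they do not state.

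The deposited matrices hold raw UMI counts per gene and nucleus, which were tested to be whole numbers, and are the only expression values used here. The deposited mapping of 28460 nuclei to the Allen 10x whole mouse brain taxonomy gives a class and subclass for each nucleus and a bootstrap probability, a fraction between 0 and 1 made by the authors' mapping run. The authors' differential expression table holds log2 fold changes of trained over naive nuclei in each of 25 Leiden clusters, from scVI over all nuclei of the 4 libraries together, with condition as a covariate of the clustering. Its log base was checked against the ratio of the table's own group means. The 4 matrices share 21154 of the 27083 gene symbols found in any of them, and only the shared genes were used.

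Groups came from the labels: trained and naive, with 2 libraries each. The labels give each library's replicate number as its batch, so libraries with the same number are taken as pairs in 1 of the fits. Across genes, log2 differences of replicate 1 and 2 within the naive group and within the trained group had a Pearson r of 0.0815 over 14759 genes of the LSX GABA class and 0.194 over the 9231 with at least 10 CPM (0.0933 and 0.254 in all neurons). Genes are not independent replicates. The fit chosen before the data were examined has no block, and blocked counts stand beside the results that they move by over 1.5 times. Libraries of 1 group were checked not to be copies of each other (chi-square per degree of freedom 2.65 for the naive and 1.73 for the trained pair).

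Counts were summed per library in each group of nuclei: all neuronal classes together, the 8 taxonomy classes (of 30 with nuclei) and the 6 lateral septum subclasses that had at least 50 nuclei in every library. Summed counts of the LSX GABA class were 14257147 and 17372933 UMIs (naive) and 2110194 and 3933027 UMIs (trained). Each comparison used edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test) with Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes mean higher in trained nuclei. CPM are TMM-scaled unless a level in a class is given per library, where they are UMIs scaled to a class sum of 1e6. Interactions were fitted as the difference of the training effect between neurons and non-neuronal nuclei, or between 1 lateral septum subclass and the other LSX nuclei, with Benjamini-Hochberg adjusted p.

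The comparisons, the naming rule, 27 gene lists and most other settings were fixed before the data were examined. Lists of response genes were immediate early genes, later activity-response genes, glucocorticoid-response genes, heat shock and chaperone genes and circadian clock genes. Lists of neuronal function were steroid hormone receptors and cofactors, glutamate receptors, GABA receptors, synthesis and transport, voltage-gated ion channels, neuropeptides and their receptors, synaptic adhesion genes, and cAMP, calcium and MAPK signalling. Lists of metabolism were mitochondrially encoded, nuclear-encoded oxidative phosphorylation and cytosolic ribosomal protein genes. Marker lists covered lateral septum, striatal projection, medial septum cholinergic and glutamatergic neurons, astrocytes, oligodendrocytes and their precursors, and microglia. They also covered endothelial and mural cells, fibroblasts and meninges, ependyma and choroid plexus, and blood. Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the lists). They were also tested with an estimated correlation, and with fry, whose directional p asks whether members move 1 way and does not compare the list with other genes. In LSX GABA nuclei, counts over all genes and adjusted over the list alone stand beside each called list.

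Named genes followed a fixed rule. Of the immediate early gene list, called members and always Fos, Arc, Egr1, Npas4, Nr4a1 and Junb were named. In LSX GABA and all neurons the 10 largest rises and falls were named among genes with adjusted p under 0.05, at least 10 CPM on average and both trained libraries on the same side of both naive libraries. In each other group the 3 largest each way were named, from each called list the 4 members with the smallest p, and from each interaction the 5 smallest p. Predicted or numbered loci were counted but not named. A few genes that met the rule are not reported here by name, though counts and list tests include them. Genes compared across groups beyond this rule, such as Fkbp5, were chosen after their values were seen, and the text says so. Of 158 named genes 84 overlap another annotated gene, 46 on the same strand (GENCODE M21), and reads shared with such neighbours were not separated.

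Shares of nuclei per class (12 classes) and subclass (24 subclasses with at least 50 nuclei over all libraries) were tested with edgeR on numbers of nuclei, without TMM scaling. Shares of nuclei with an immediate early gene UMI were taken after thinning every nucleus to 1000 UMIs, with shallower nuclei left out, and compared with an exact permutation test over the 4 libraries (6 arrangements, smallest two-sided p 0.333). Intervals are exact Clopper-Pearson at 95%, the floor of a count of 0 is 3 counts, and both cover counting error only.

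Other settings fixed beforehand were DESeq2 1.42.0, scaling by library size alone, no filter on low counts, at least 10 CPM in 2 libraries, leaving out each library and the replicate number as a block. Depth was varied by thinning of the sums or of each nucleus (1000 or 500 UMIs). Nuclei were varied by leaving out scrublet doublets, by a bootstrap probability of at least 0.9 and by oligodendrocytes as the only non-neuronal nuclei. Further settings were leaving out mitochondrially encoded genes and Malat1, TMM scaling of numbers of nuclei and an adjusted p of 0.01 for the comparison with the authors' table. Scrublet (scanpy 1.11.5) marked 0.232%, 0.122%, 0.222% and 0.281% of nuclei in naive 1 and 2 and trained 1 and 2, too few to have worked, so leaving out the 5% with the highest scores was added after the data were seen. Grouping nuclei by the majority class or subclass of their Leiden cluster was added then too.

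The procedure was tested on simulated counts with the gene means, library sizes and spread of these data. In LSX GABA, edgeR recovered 40.9%, 63.6% and 90.9% of genes changed by 1.5-, 2- and 4-fold and called 4 unchanged genes (0.0279% of the unchanged genes tested), and the interaction test recovered 42.6% of genes changed 2-fold in neurons alone. The simulated counts followed the kind of model that edgeR fits and held no shift between groups beyond the set folds. They therefore do not tell how many genes called in the real data are false. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 20240. Chromatin accessibility, the cluster marker table, the latent coordinates and the neighbour graph were not analysed here, apart from numbers of peak counts per called nucleus. Classes with fewer than 50 nuclei in a library had no comparison of expression of their own, while those of neurons entered the sum of all neurons.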

Results

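Nuclei came from the lateral septum, a forebrain region made up largely of GABAergic neurons, of adult female C57BL/6J mice in proestrus, a stage of the ovarian cycle. Per the labels' protocols, mice were randomly assigned, 4 mice per group, to threat conditioning or to a naive home-cage group. Conditioned mice, called trained here, received 6 pairings of a tone (20 s, 5 kHz, 75 dB) with a shock (2 s, 0.5 mA) and were euthanised 5 min after the chamber. Punches were pooled by group before nuclei were isolated, and gene expression was counted by 10x Multiome in 2 libraries per group. The 24912 nuclei kept by the authors were 6886 and 6571 in the naive libraries and 5409 and 6046 in the trained libraries. Total UMIs in these nuclei were 20130125 and 24561995 in the naive libraries against 3439613 and 6198011 in the trained libraries. Median UMIs per nucleus were 2157 and 2676 (naive) against 426 and 650 (trained), a 4.49-fold difference (exact permutation test, two-sided p = 0.333, the smallest p that 2 libraries a group allow). Median genes per nucleus were 1278.5 and 1469 (naive) against 341 and 485 (trained).

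**Figure D1:**
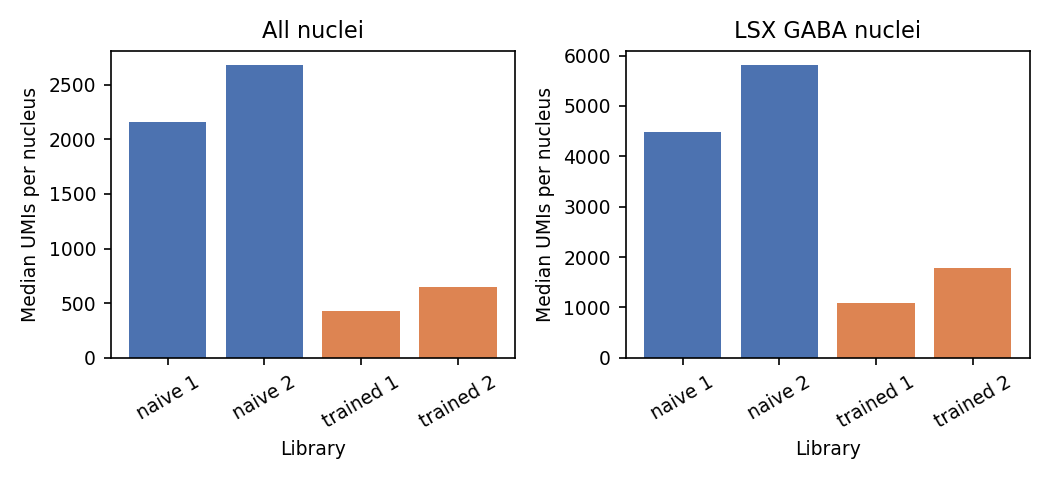
Median UMIs per nucleus (y axes) in each library (bars), over all nuclei on the left and over LSX GABA nuclei on the right, naive in blue and trained in orange. Both trained libraries, at 426 and 650 over all nuclei, lay below both naive libraries, at 2157 and 2676.

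The mapped classes below each carried a marker of their type in all 4 libraries, while Immune, CNU-LGE GABA and CNU-HYa GABA are not shown. A marker's presence does not show that a class is free of nuclei of other types. In the LSX GABA class, the GABAergic neurons of the lateral septum and the main subject here, Trpc4, a cation channel gene of these neurons, stood at 1062 and 1065 CPM (naive) and 974 and 1014 CPM (trained). Slc17a6, the vesicular glutamate transporter of glutamatergic neurons, was at 385 and 345 CPM (naive) and 364 and 382 CPM (trained) in the CNU-HYa Glut class. Mbp, a myelin protein, was at 3699 and 3583 CPM (naive) and 3891 and 4318 CPM (trained) in OPC-Oligo nuclei. Flt1, an endothelial receptor, was at 1225 and 1287 CPM (naive) and 1169 and 1376 CPM (trained) in Vascular nuclei. Slc1a2, the astrocytic glutamate transporter, was at 5892 and 6114 CPM (naive) and 4734 and 4612 CPM (trained) in Astro-Epen nuclei.

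The first question was which genes differed between trained and naive lateral septum neurons shortly after conditioning. Immediate early genes, which neurons switch on within minutes of activity, made up a far larger share of UMIs in trained LSX GABA nuclei. Levels here are relative to all UMIs, and trained LSX GABA nuclei were shallower. Their median depths were 1097 and 1784 UMIs, against 4486 and 5805 UMIs in naive libraries. Among genes with at least 10 CPM on average, Fosb and Fos, both AP-1 transcription factor subunits, rose most. Fosb was at 44.8 ± 11.1 CPM in trained against 2.0 ± 0.234 CPM in naive libraries (SD, n = 2 libraries per group, as for all values below). Fos was at 74.1 ± 11.8 against 4.94 ± 0.705 CPM. The activity-dependent transcription factor Npas4 rose from 12.7 ± 0.855 to 79.7 ± 0.0851 CPM, and Arc, which acts at synapses in plasticity, from 12.9 ± 2.07 to 76.4 ± 4.6 CPM. Nts, the precursor of the neuropeptide neurotensin, rose from 61.1 ± 15.7 to 250.3 ± 3.86 CPM. By the edgeR quasi-likelihood test, 1266 of 14759 tested genes passed an adjusted p of 0.05, 904 higher and 362 lower in trained nuclei.

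The log2 fold changes (± SE) were 4.42 ± 0.21 for Fosb (21.4-fold, edgeR adjusted p = 1.93e-17) and 3.86 ± 0.15 for Fos (14.6-fold, edgeR adjusted p = 2.36e-19). The other large rises by the naming rule were Gem, a small GTPase that restrains calcium channels (3.27), Fosl2 (3.22), the antiproliferative gene Btg2 (3.2), the transcription factor Egr3 (3.17) and the orphan nuclear receptors Nr4a3 (3.10) and Nr4a2 (2.86). The MAP kinase phosphatase Dusp1 (2.98) and Junb (2.80) completed them. Fos lies on chromosome 12 (mm10, 85473890 to 85477273, ENSMUSG00000021250) and Fosb on chromosome 7 (19302696 to 19310051, ENSMUSG00000003545). Npas4 lies on chromosome 19 (4984355 to 4990316, ENSMUSG00000045903), Arc on chromosome 15 (74669083 to 74672570, ENSMUSG00000022602) and Nts on chromosome 10 (102481756 to 102490486, ENSMUSG00000019890). All are annotated as protein coding. Of 32 measured immediate early genes, 29 rose, none fell and 3 did not pass the test (Ier5, Klf6 and Klf10, with log2 changes of 0.31, 0.52 and 1.04). The list's median log2 change was 2.5, its count adjusted over the list alone was 31, and its Benjamini-Hochberg adjusted p by camera was 3.05e-254, or adjusted p = 0.0515 with an estimated correlation. Egr1 (2.24), Nr4a1 (2.09), Egr4 (2.69), Egr2 (3.77), Atf3 (3.88), Trib1 (2.60), Ier2 (2.59), Gadd45b (2.44), Csrnp1 (2.34) and Apold1 (2.33) rose as well. So did Dusp6 (1.62), Per1 (1.58), Jun (1.42), Klf4 (1.23), Homer1 (1.17), Gadd45g (1.16), Sik1 (1.07) and Jund (0.73). The edgeR adjusted p of these members ran from 6.80e-18 for Egr4 to 0.0332 for Klf4. Summed over the list, oligodendrocyte markers in these nuclei stood in the 2 trained libraries at 1.22 and 1.39 times the naive mean, against 3.97 and 3.59 times for the immediate early genes.

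**Figure D2:**
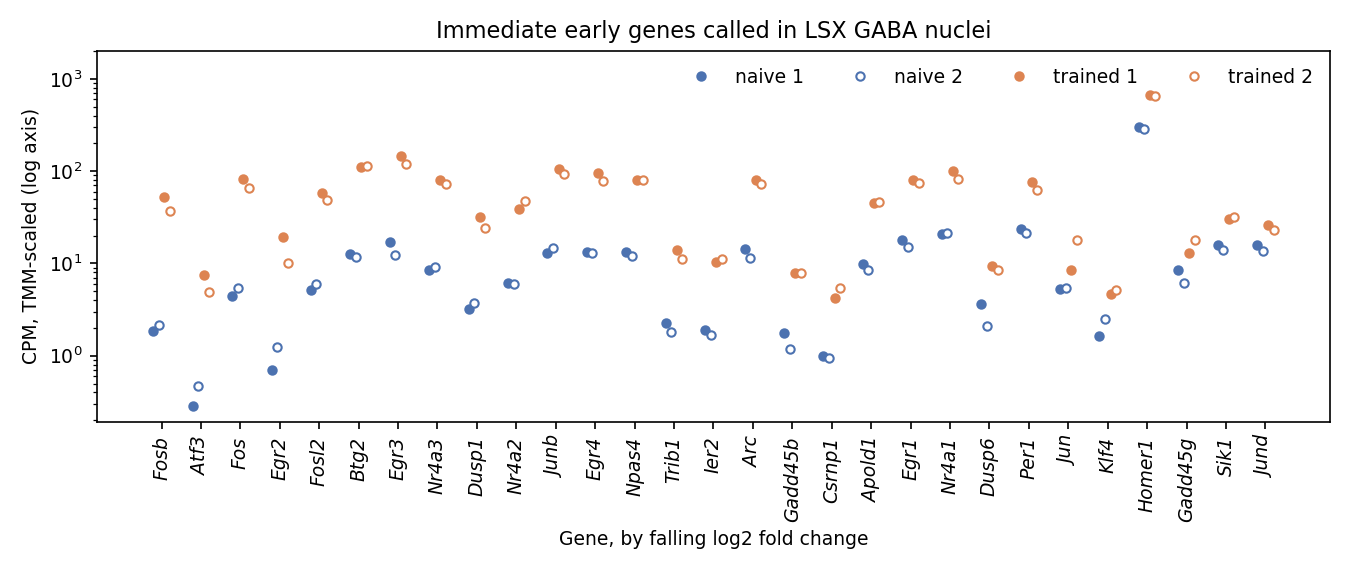
TMM-scaled CPM on a log axis of the 29 immediate early genes that rose in LSX GABA nuclei, ordered by log2 fold change, with 1 point per library (naive in blue, trained in orange). Each of these genes was higher in both trained libraries than in both naive libraries, and Fos averaged 74.1 against 4.94 CPM.

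Other lists fixed before the data were examined moved too, each by less. Of 17 measured later activity-response genes 12 rose, 12 adjusted over the list alone. Among them were the prohormone convertase Pcsk1 (log2 1.52), the granin Scg2 (1.30, 60.1 ± 8.56 to 147 ± 10.2 CPM), the histone demethylase Kdm6b (1.15) and the neuropeptide precursor Vgf (1.06). Their Benjamini-Hochberg adjusted p by camera was 3.97e-22, and adjusted p = 0.0822 with an estimated correlation. Of 27 neuropeptides and receptors 6 rose, 6 adjusted over the list alone, led by Nts (2.04), Cartpt (1.64), Sst (1.32, somatostatin, 142 ± 40.8 to 361 ± 74.7 CPM) and Penk (1.07, enkephalin precursor). Camera gave a Benjamini-Hochberg adjusted p of 2.58e-08, and adjusted p = 0.143 with an estimated correlation. Of 13 heat shock and chaperone genes 8 rose, 8 adjusted over the list alone, led by the co-chaperones Dnajb1 (2.42, 5.68 ± 0.342 to 31.3 ± 5.75 CPM) and Dnaja1 (1.06), then Hspa8 (0.47) and Hspa5 (0.43). Their Benjamini-Hochberg adjusted p by camera was 9.07e-12, and adjusted p = 0.146 with an estimated correlation. Of 13 glucocorticoid-response genes 4 rose, 6 passing adjusted over the list alone (5 up, 1 down): the cell cycle inhibitor Cdkn1a (2.17), the clock gene Per1 (1.58), Errfi1 (1.29), which restrains EGF receptor signalling, and the metallothionein Mt1 (0.67). These 4 are also induced by other signals. The list's camera Benjamini-Hochberg adjusted p was 6.33e-05, and adjusted p = 0.333 with an estimated correlation. Fkbp5, a chaperone that glucocorticoids induce, was at 59.9 ± 0.107 CPM naive and 49.8 ± 6.44 CPM trained (edgeR adjusted p = 0.165), and Zbtb16 had a log2 change of -0.36 (edgeR adjusted p = 0.0975). Of 17 circadian clock genes 5 rose, 5 adjusted over the list alone, with Per1, Bhlhe40 (1.38), Rorb (1.36) and Ciart (0.99) the smallest in p, a camera Benjamini-Hochberg adjusted p of 0.000476 and adjusted p = 0.22 with an estimated correlation.

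Transcripts of energy metabolism and translation were modestly higher in trained LSX GABA nuclei. Of 11 mitochondrially encoded genes 6 rose, among them mt-Atp6 (log2 0.51), mt-Co2 (0.46), mt-Nd1 (0.45) and mt-Co3 (0.43), while mt-Nd5, named after its value was seen, fell by 1.62; 9 passed adjusted over the list alone (7 up, 2 down). Of 30 nuclear-encoded oxidative phosphorylation genes 8 rose (12 adjusted over the list alone), with Ndufa4 at 0.54, Uqcrb at 0.53, Atp5j at 0.42 and Cox7c at 0.36. Of 45 cytosolic ribosomal protein genes 8 rose (15 adjusted over the list alone), with Rpl19 at 0.58, Rpl41 at 0.53, Rpl13 at 0.45 and Rplp1 at 0.42. The camera Benjamini-Hochberg adjusted p values of these 3 lists were 0.00145, 0.00541 and 6.87e-05, and with an estimated correlation the adjusted p values were 0.333, 0.518 and 0.39. Mitochondrially encoded genes rose beyond this class too, 5 of 10 in CNU-HYa Glut, 5 of 10 in Astro-Epen and 3 of 10 in OPC-Oligo nuclei. Their share of UMIs was 0.164% in trained and 0.106% in naive libraries, with 10.7% and 7.52% of UMIs outside called nuclei. The shortest 25% of tested genes had a median log2 change of 0.17 in LSX GABA nuclei, and no cause of these rises was tested.

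Genes of synapses and excitability were lower in trained LSX GABA nuclei by small amounts. Of 33 synaptic adhesion genes 11 fell and 1 rose (20 adjusted over the list alone, 19 of them down). The contactins Cntn5 (log2 -0.25, 981 ± 13.6 to 826 ± 3.19 CPM) and Cntn6 (-0.27) and Il1rapl2 (-0.24) fell, and Nlgn2, the neuroligin of inhibitory synapses, rose (0.36). Of 39 voltage-gated ion channel genes 8 fell (9 adjusted over the list alone), with Kcnip4, a potassium channel partner, at -0.31, Kcnh1 at -0.34, Cacnb2 at -0.21 and Kcnd2 at -0.19. Of 23 glutamate receptor genes 4 fell (10 adjusted over the list alone, 8 down and 2 up), among them the kainate receptor subunits Grik2 (-0.25) and Grik4 (-0.54) and Grid1 (-0.25). Camera gave Benjamini-Hochberg adjusted p values of 1.96e-07, 9.56e-05 and 0.00051 for the 3 lists, and with an estimated correlation adjusted p = 0.303 for each. The 95 members tested were long genes (median 385 kb against 25.5 kb over all tested genes), and across genes, which are not independent replicates, log2 changes fell with gene length (Spearman rho -0.287). The members' median log2 change of -0.11 was -0.04 with every nucleus thinned to 1000 UMIs, and random lists matched on length and mean expression had a median of -0.10. The largest single falls by the naming rule were Chd1l, a chromatin remodeller (-0.91, 13.3 ± 1.78 to 7.17 ± 0.404 CPM), Mad1l1 (-0.87), the mitochondrial aspartate-glutamate carrier Slc25a13 (-0.85) and Pskh1 (-0.81). Anks6 (-0.75), Tipin (-0.73), Denr (-0.71), Mrnip (-0.70), Amot (-0.69) and the transcription factor Nfix (-0.67) followed, with edgeR adjusted p from 0.00129 for Slc25a13 to 0.034 for Tipin. Chd1l lies on chromosome 3 (mm10, 97560742 to 97610203, ENSMUSG00000028089) and Kcnip4 on chromosome 5 (48389502 to 49524907, ENSMUSG00000029088).

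The 16 lateral septum neuron markers were split: Nts and Sst rose, the chloride channel Ano2 fell (-0.29), and Zic1 had a log2 change of 0.18 (edgeR adjusted p = 0.101), and one of 0.19 that passed with the replicate block. Their median log2 change was -0.04, their mean 0.18 and the camera test upward (Benjamini-Hochberg adjusted p = 0.0317, and adjusted p = 0.303 with an estimated correlation), with 3 passing adjusted over the list alone. In all, 13 of 19 testable lists were called by camera (10 up, 3 down), 0 with an estimated correlation, and 4 by the directional fry test. Lists not called included steroid hormone receptors and cofactors (Benjamini-Hochberg adjusted p by camera 0.406), where Pgrmc1 was the 1 of 16 that rose. Among 19 genes of GABA receptors, synthesis and transport (0.719), Gad1 and Slc32a1 rose and Gabrb1 fell, with 10 adjusted over the list alone. Of 32 genes of cAMP, calcium and MAPK signalling (0.972), Pde10a and Prkar1a were among those that rose, with median and mean above 0 and the test downward. Enpp2 rose among 7 ependymal and choroid plexus markers (0.556) and none of 5 medial septum cholinergic markers (0.78). Pecam1, 1 of 2 measured endothelial and mural markers, rose (1.22), and 0 of the measured glutamatergic (1), astrocyte (4), oligodendrocyte (3), oligodendrocyte precursor (2), microglia (4), fibroblast (1) and blood (1) markers passed edgeR. These members of uncalled lists were chosen after their values were seen. The count of 1266 genes was 429 without naive replicate 2 and 804 without trained replicate 1 and 467 by DESeq2 (all among the 1266). It was 358 with every nucleus thinned to 1000 UMIs (325 of them among the 1266) and 2141 with the replicate number, which the labels also give as the batch, as a block. Such p values measure only the spread between libraries made from pooled punches, not between mice.

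**Figure D3:**
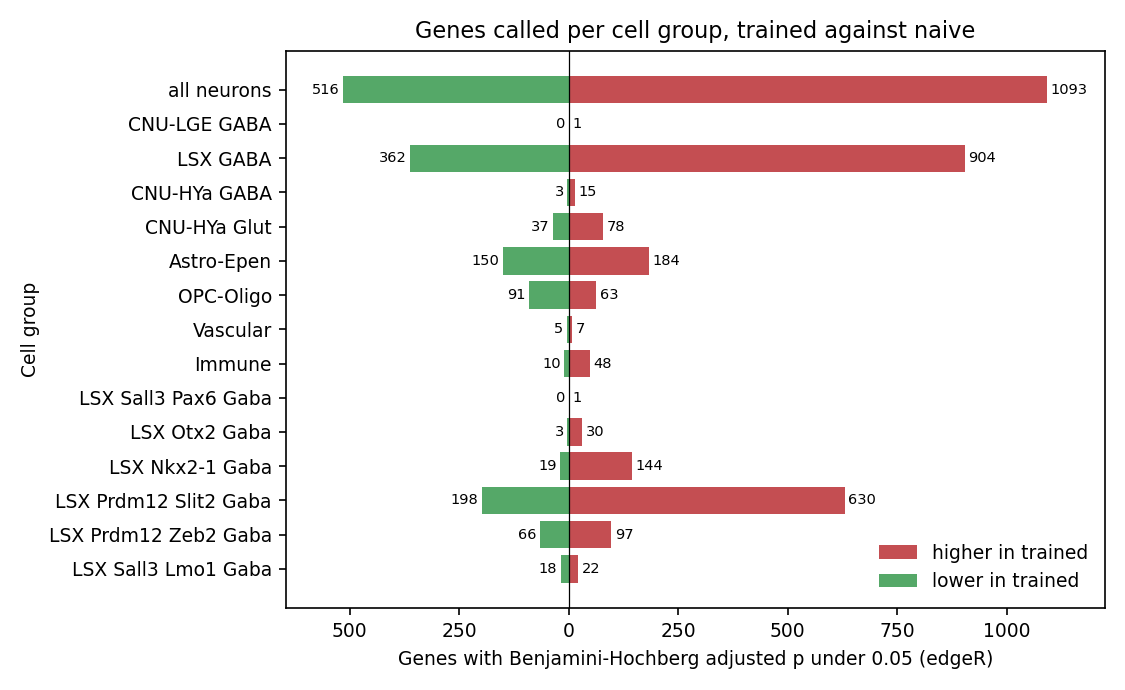
Numbers of genes with an edgeR Benjamini-Hochberg adjusted p under 0.05 (x axis) in each cell group (y axis), drawn to the right for higher and to the left for lower in trained nuclei. LSX GABA had 904 higher and 362 lower, and CNU-LGE GABA and LSX Sall3 Pax6 had 1 gene each.

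With all neuronal classes summed, the same question gave immediate early genes and myelin transcripts as the largest rises. Ptgds, a prostaglandin synthase, stood at 102 ± 70.6 CPM trained against 2.31 ± 2.06 CPM naive, and Apoe, a glial lipid carrier, at 49.5 ± 39.9 against 1.01 ± 0.0866 CPM. Fosb (log2 4.14), Fos (3.75, 4.94 ± 0.315 to 68.0 ± 10.9 CPM), Egr3 (3.13) and Fosl2 (3.08) also rose, beside Mal (5.78), Apod (4.64) and Trf (4.44). In all 1609 of 15548 genes passed edgeR, 1093 up and 516 down. Of 10 oligodendrocyte markers 9 rose, 10 adjusted over the list alone (median 4.46, with Cldn11 at 6.54, Mal at 5.78 and Mag at 5.26). They had a camera Benjamini-Hochberg adjusted p of 3.31e-38 and adjusted p = 0.218 with an estimated correlation. Of 11 microglia markers 7 rose (the complement genes C1qc at 3.27, C1qb at 3.01 and C1qa at 2.34, and the protease Ctss at 2.10), 9 adjusted over the list alone. Their list had a camera Benjamini-Hochberg adjusted p of 1.34e-08 and adjusted p = 0.348 with an estimated correlation. Of 5 endothelial and mural markers Vtn (1.94) and Pecam1 (1.23) rose, 2 adjusted over the list alone, with a camera Benjamini-Hochberg adjusted p of 0.0124 and adjusted p = 0.292 with an estimated correlation. The summed oligodendrocyte markers of neurons were at 36.9 and 30.9 CPM (naive) and 589.6 and 200 CPM (trained) by mapped class. With nuclei grouped by the majority class of the authors' Leiden clusters, an alternative added after the data were seen, they were at 35.3 and 27.9 CPM (naive) and 40.7 and 37.5 CPM (trained). So grouped, the microglia list had a median log2 change of -0.15, against 1.92 by mapped class, and C1qa one of -0.68. Of 33 immediate early genes 31 rose, 33 adjusted over the list alone, and adjusted p = 0.0905 with an estimated correlation. The largest falls were Pskh1 (-0.83), Mad1l1 (-0.78), Anks6 (-0.73), Mrnip (-0.72), Adamts18 (-0.72), Cryl1 (-0.69), Nup133 (-0.68), Trmt9b (-0.67), Lrsam1 (-0.66) and Corin (-0.66).

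Camera called 15 of 23 lists in all neurons (12 up, 3 down), 0 with an estimated correlation and 2 by fry. With the replicate block it called 17, adding lateral septum neuron and astrocyte markers (Benjamini-Hochberg adjusted p by camera 0.0108 and 0.0369). Beside the lists above, later activity-response (14 of 18), neuropeptide (9 of 29), heat shock (8 of 13) and glucocorticoid-response genes (6 of 14) rose. So did mitochondrially encoded (7 up and 1 down of 11), oxidative phosphorylation (10 of 30), ribosomal protein (14 of 45) and clock genes (5 of 17). Synaptic adhesion (12 down and 1 up of 33), glutamate receptor (6 of 23) and ion channel genes (7 of 39) fell. With an estimated correlation their adjusted p values ran from 0.118 for the later activity-response genes to 0.424 for oxidative phosphorylation. Without naive replicate 2 the count of 1609 was 488, and without trained replicate 1 it was 549, with 585 by DESeq2, 405 with nuclei thinned to 1000 UMIs, 945 with the sums thinned and 2750 with the replicate block. Of the 1609, 67.9% were up, and 80.4% of those called were up under scaling by library size alone.

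In 2 of the 3 other neuronal classes immediate early genes stood among the largest rises. In CNU-HYa GABA nuclei, Nr4a2 rose from 3.63 ± 1.86 to 108 ± 7.96 CPM (log2 4.74), though its naive level rests on 2 and 1 UMIs, under counting floors of 6.53 and 6.15 CPM. Egr3 rose by 3.89 and Junb by 3.24 on the log2 scale, while Nell1 (-0.98), the histone deacetylase Hdac9 (-0.96) and Cntnap5a (-0.74) fell. Npas4 rose there too (2.64, edgeR adjusted p = 0.013), and Fos was at 87.4 ± 20.6 CPM against 13.5 ± 15.8 CPM (edgeR adjusted p = 0.077). In CNU-HYa Glut nuclei, Fos rose from 3.53 ± 1.10 to 31.3 ± 0.96 CPM (3.09) and Egr1 from 5.38 ± 0.168 to 47.5 ± 14.2 CPM (3.04). Neuropeptide Y, Npy, rose by 2.88, resting on 8 and 2 naive and 3 and 15 trained UMIs. Chst9 (-2.03) and Plce1 (-2.0) were among the largest falls there, resting on 1 and 5 and on 0 and 6 trained UMIs. In CNU-LGE GABA nuclei the 1 gene called was Il1rapl2, a synaptic adhesion gene, at 225 ± 31.7 CPM trained against 5.10 ± 2.0 CPM naive. It rests on 1 and 2 UMIs against 13 and 25 UMIs, and was not called with nuclei grouped by cluster. By edgeR, 18 genes (15 up, 3 down) passed in CNU-HYa GABA, with 39 without naive replicate 2, 8 without trained replicate 2, 7 by DESeq2 and 45 with the replicate block. Of the 39, 17 were up and 22 down, and with no filter on low counts 15 were up and 15 down. In CNU-HYa Glut 115 passed (78 up, 37 down), with 8 without naive replicate 2, 42 without trained replicate 1, 33 without trained replicate 2 and 13 by DESeq2, and its share up of 67.8% was 83.0% under library size alone, 46.2% by DESeq2, 50.6% with no filter on low counts and 52.3% without naive replicate 1. The CNU-LGE GABA count was 2 without naive replicate 1, 7 without naive replicate 2 and 16 without trained replicate 2.

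Astrocytes and ependymal cells, mapped as Astro-Epen, also had immediate early genes as their largest rises, and several glucocorticoid-response genes fell. Fos rose from 6.87 ± 2.55 to 124 ± 6.33 CPM (log2 4.10, edgeR adjusted p = 7.22e-11), Nr4a1 from 8.56 ± 0.157 to 95 ± 23.9 CPM (3.39) and Nr4a3 by 3.32, and 11 of 19 measured immediate early genes rose. Arhgef37 (-2.04), Errfi1 (-1.92) and the deubiquitinase Uchl5 (-1.89) had the largest falls. Fkbp5 fell from 267 ± 25 to 87.1 ± 25.5 CPM (-1.70, edgeR adjusted p = 8.09e-08) and Hif3a, a hypoxia-inducible factor subunit, by 1.25 on the log2 scale (edgeR adjusted p = 2.73e-05), both chosen after their values were seen. Of 16 measured glucocorticoid-response genes 4 fell and 1 rose. Choroid plexus transcripts rose in the same class, chosen after their values were seen. Ttr, transthyretin, was at 360 and 591 CPM naive against 3529 and 2572 CPM trained, and Htr2c, a serotonin receptor, at 213 and 146 against 844 and 883 CPM. Choroid plexus cells had a larger share of nuclei in trained libraries, as given below, and these rises were not separated from that shift. In all, 334 genes passed edgeR (184 up, 150 down), 187 without naive replicate 2, 115 by DESeq2, 219 by clusters and 511 with the replicate block. The share up went from 55.1% to 67.7% under library size alone.

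In oligodendrocytes and their precursors, 7 of 16 measured glucocorticoid-response genes fell and none rose. None of 8 measured immediate early genes passed edgeR (median log2 change 0.01), with Nr4a1 at 16.9 ± 6.05 CPM trained and 15.2 ± 3.33 CPM naive. Cdkn1a fell from 21.7 ± 3.12 to 0.816 ± 1.15 CPM (log2 -4.19), which rests on 0 and 1 UMIs in the trained libraries, whose counting floors were 9.58 and 4.8 CPM. Fkbp5 fell from 215 ± 14.5 to 110.3 ± 17.1 CPM (-0.91, edgeR adjusted p = 0.000227). Zbtb16 fell from 406 ± 55.1 to 236 ± 11.9 CPM (-0.77) and Hif3a by 1.28 on the log2 scale. Fkbp5, Zbtb16 and Hif3a were chosen after their values were seen. Phyhd1 (-2.51) and the metabolic coactivator Ppargc1a (-2.39) fell too, resting on 5 and 1 and on 1 and 3 trained UMIs. Upk3bl (2.17), Trim30a (1.85) and the MHC class I gene H2-D1 (1.43, 32.2 ± 2.19 to 86.8 ± 1.86 CPM) rose most. In OPC-Oligo 154 genes passed edgeR (63 up, 91 down), 60 without naive replicate 2, 67 by DESeq2, 242 by clusters and 321 with the replicate block.

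In Vascular nuclei the small heat shock protein Hspb1 (log2 2.17), Mgat4c (2.11) and the aldehyde oxidase Aox3 (2.10) rose, and Slit2 (-3.00), Pcdh7 (-2.54) and the bicarbonate transporter Slc4a10 (-2.39) fell. These falls rest on few trained UMIs, 1 and 2 for Slit2, 3 and 4 for Pcdh7 and 4 and 12 for Slc4a10. So do the 3 rises, on 6 and 16 for Hspb1, 6 and 28 for Mgat4c and 6 and 17 for Aox3. Fkbp5 (-2.06, edgeR adjusted p = 0.0218) and Malat1 (-0.41) made up the rest of the 5 falls, both chosen after their values were seen, beside 7 rises, or 12 genes in all. With nuclei grouped by cluster 28 genes passed, only 1 of them among the 12, and Slit2 (0.02) and Slc4a10 (0.06) had log2 changes above 0. The count of 12 was 0 without naive replicate 2, 38 without trained replicate 1, 21 without trained replicate 2 and 0 by DESeq2, where 199 genes had an unadjusted p under 0.05 in edgeR. It was 40 with the replicate block, while 0 rose and 9 fell with no filter on low counts, and 0 rose and 10 fell with at least 10 CPM in 2 libraries. In Immune nuclei, mostly microglia, the neuronal and oligodendrocyte genes Nkain2 (5.34, 27.6 ± 8.04 to 1152 ± 28.2 CPM), Pcdh9 (4.63) and Ncam2 (4.19) rose most. Slc10a7 (-3.72) and Hipk1 (-3.54) fell, each resting on 0 and 1 UMIs in the trained libraries. Bfar was at 124 ± 4.16 CPM naive with 0 UMIs in both trained libraries, whose counting floors were 92.1 and 47.9 CPM. Fkbp5 fell there from 1666 ± 142 to 876 ± 134 CPM (-0.89, edgeR adjusted p = 0.0106), chosen after its value was seen. Summed oligodendrocyte markers in Immune nuclei were at 361 and 256 CPM naive against 3713 and 2332 CPM trained. The Immune count of 58 (48 up, 10 down) was 23 without naive replicate 1, 19 without naive replicate 2, 36 without trained replicate 2, 22 by DESeq2 and 3 by clusters.

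Within the lateral septum, subclasses named by marker genes in the taxonomy differed in how many genes passed, and also in depth. Trained libraries held 676603 and 1241900 UMIs in LSX Prdm12 Slit2 nuclei and 474535 and 904752 in LSX Nkx2-1 nuclei. They held 450509 and 857106 in LSX Prdm12 Zeb2 and 242922 and 395143 in LSX Sall3 Lmo1 nuclei. In LSX Otx2 they held 172042 and 352357, and in LSX Sall3 Pax6 93583 and 181769. Fewer UMIs leave fewer changes detectable, so numbers of genes passing do not rank subclasses by response. Nuclei of the LSX Prdm12 Slit2 subclass had the most genes passing. Fosb rose from 4.22 ± 0.448 to 108 ± 28.9 CPM (log2 4.61), Egr2 by 4.39, Fos from 9.35 ± 0.716 to 147 ± 21.3 CPM (3.93) and Npas4 from 12.8 ± 0.473 to 158 ± 5.15 CPM (3.61), with 28 of 31 immediate early genes up. Drc3 (-1.57), Flrt1 (-1.46) and Epb41l2 (-1.34) fell most. In LSX Nkx2-1 nuclei, Fosb (4.70), Fos (4.19) and Nr4a2 (3.85) rose and Uqcrc2 (-0.97), Zfp799 (-0.97) and Mios (-0.87) fell, with 20 of 26 immediate early genes up. In LSX Otx2 nuclei, Fosb (4.62), Cdkn1a (4.10) and Fos (3.98) rose, with 14 of 19 immediate early genes up. Pdzd2 (-0.98), the ephrin receptor Epha5 (-0.53) and Lsamp (-0.27, not passing with the replicate block) fell there. Fosb rests there on 0 and 4 naive and 8 and 7 trained UMIs, and Cdkn1a on 3 and 2 against 5 and 8. In LSX Prdm12 Zeb2 nuclei, Fos (2.94, 3.29 ± 0.712 to 27.4 ± 10.7 CPM), Afm (2.27) and Btg2 (2.22) rose and Cab39l (-1.11), Atg10 (-0.90) and Ptprz1 (-0.83) fell, with 9 of 25 immediate early genes up. Npas4 was at 16.5 ± 4.77 CPM against 9.35 ± 0.625 CPM (edgeR adjusted p = 0.318). In LSX Sall3 Lmo1 nuclei, Slc15a2 (2.94), Apold1 (2.28) and Arc (2.14) rose. Sntg2 (-2.38, resting on 2 and 3 trained UMIs), Slc24a2 (-1.36) and Dph6 (-1.32) fell, with 3 of 14 immediate early genes up. In LSX Sall3 Pax6 nuclei 0 of 7 passed edgeR, and the 1 gene called was the predicted locus 1700016P03Rik (2.29), named after its value was seen. By edgeR 828 genes passed in Slit2 (630 up, 198 down), with 524 without naive replicate 1, 302 without naive replicate 2, 495 without trained replicate 1 and 245 by DESeq2. In Nkx2-1 163 passed (144 up, 19 down), against 72 by DESeq2. In Zeb2 163 passed (97 up, 66 down), with 66 without naive replicate 2 and 52 without trained replicate 1. Counts were 40 for Lmo1 (22 up, 18 down), with 77, 12, 20 and 21 without naive replicate 1, naive replicate 2, trained replicate 1 and trained replicate 2. For Pax6 they were 1, with 1, 4, 3 and 3 in that order, and for Otx2 33 (30 up, 3 down), with 0, 0, 62 and 87. Of these 87, 34 were up and 53 down, and with no filter on low counts 43 were up and 64 down in Otx2. With the replicate block, counts were 401 in Nkx2-1, 371 in Zeb2 (186 up, 185 down), 51 in Otx2 and 9 in Pax6. Under library size alone the share up went from 59.5% to 72.8% for Zeb2 and from 55% to 68.6% for Lmo1.

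Whether the response to training differed between subclasses was tested as an interaction, each subclass against the other LSX nuclei. A positive difference means a higher log2 change in the subclass than in the other nuclei, and a negative one a lower. A lower log2 change can be a smaller rise or a larger fall. The other nuclei include Slit2 nuclei when another subclass is tested. Of 98 genes that differed in the Slit2 subclass, 93 had a higher log2 change there. They were led by Tiparp, an activity-induced mono-ADP-ribosyltransferase (difference of log2 changes 1.87, edgeR adjusted p = 3.22e-15), Homer1, a postsynaptic scaffold (0.97), Zdbf2 (0.93), the neurofilament protein gene Ina (1.24) and Sst (0.85). Of 32 immediate early genes 12 had a higher log2 change in Slit2 nuclei and 0 a lower one, among them Npas4 (1.80, edgeR adjusted p = 1.89e-07), Egr1 (1.01), Junb (0.97), Nr4a1 (0.94) and Arc (0.93). Fos differed by 0.27 (edgeR adjusted p = 0.872). Zeb2 nuclei had a lower log2 change at 48 of 58 genes, with Tiparp at -2.08, Homer1 at -1.16, Sst at -0.87, Zdbf2 at -0.82 and Rheb at -1.18. There 7 of 32 immediate early genes had a lower log2 change, such as Npas4 (-1.93) and Arc (-1.63). Lmo1 nuclei had a lower log2 change at 22 of 23 genes, with Tiparp at -1.95, Homer1 at -0.93, Ina at -2.43, Cartpt at -4.47 and Rheb at -1.46. The difference alone does not tell whether these genes rose less or fell in Lmo1 nuclei. In Pax6 nuclei 6 genes differed, with Scg2 at -1.64, Zdbf2 at -1.09, Homer1 at -0.97, Chrm2 at -0.91 and Hs6st3 at -0.58. In Otx2 nuclei 1 differed, Epha5 (-0.51), whose own log2 change there was -0.53. In Nkx2-1 nuclei 0 of 12938 genes passed edgeR, with 690 at an unadjusted p under 0.05.

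Between neurons and non-neuronal nuclei, a positive difference can come from a larger rise in neurons or from a fall in non-neuronal nuclei. By edgeR 607 of 15304 genes differed in their response, 513 with the higher log2 change in neurons. Among the 5 with the smallest p were Ptgds (difference of log2 changes 5.37), Apoe (4.99), Trf (4.32) and Htr2c (-2.61). Htr2c went from 78.5 and 53.3 CPM to 336 and 353 CPM in non-neuronal nuclei and from 609 and 626 CPM to 526 and 552 CPM in neurons. The choroid plexus gene Ttr went from 129 and 214 CPM to 1412 and 1011 CPM in the same non-neuronal nuclei, whose choroid plexus cells had a 5.00-fold larger share of nuclei in trained libraries. Arc differed (3.04, edgeR adjusted p = 0.000904), with non-neuronal levels of 1.51 and 3.82 CPM naive and 1.35 and 2.14 CPM trained. Fos did not pass (-0.39, edgeR adjusted p = 0.766), with non-neuronal levels of 2.41 and 3.34 CPM naive and 51.3 and 50.6 CPM trained. Without naive replicate 1, naive replicate 2 or trained replicate 1 the count was 272, 215 or 331, and it was 115 by DESeq2 and 262 by clusters. By clusters Ptgds, Apoe and Trf were no longer among the 5 smallest p and Htr2c (-2.66), Tiparp (1.86), Ttr (-3.33), Errfi1 (1.93) and Dclk1 (-0.61) were.

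Detection of immediate early genes in single nuclei was taken as the share of nuclei with a UMI of Fos, Arc, Egr1, Npas4, Nr4a1 or Junb, with every nucleus thinned to 1000 UMIs. It does not count the neurons that responded. In LSX GABA nuclei this share was 26.2% ± 2.56 in trained and 7.39% ± 0.282 in naive libraries (exact permutation p = 0.333, two-sided, n = 2). It was 40.8% ± 4.14 against 9.63% ± 0.382 in Slit2 nuclei, and 14.7% against 5.83% in Zeb2, 24.4% against 6.82% in Nkx2-1, 21.5% against 6.46% in Otx2, 16.6% against 8.11% in Lmo1 and 13.1% against 5.81% in Pax6 nuclei. Fos alone gave 5.84% against 0.638% in LSX GABA. Thinning left 2921 and 2728 naive and 1101 and 1913 trained LSX nuclei and left out 11 and 7 naive and 710 and 203 trained ones, whose median depths were 4486 and 5805 (naive) and 1097 and 1784 UMIs (trained). Unthinned, the shares were 30% ± 3.26 trained and 28.6% ± 3.03 naive (exact permutation p = 0.667). In Zeb2, Lmo1 and Pax6 nuclei the unthinned naive shares were the higher (29.8% against 21.8%, 29.4% against 21.7% and 19.8% against 15.0%). In oligodendrocytes unthinned shares were 0.470% ± 0.525 trained and 2.14% ± 0.782 naive at median depths of 201 and 328 (trained) and 791 and 1017 UMIs (naive). Only 2 and 19 trained oligodendrocytes reached 1000 UMIs, so no background share is given at that depth.

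**Figure D4:**
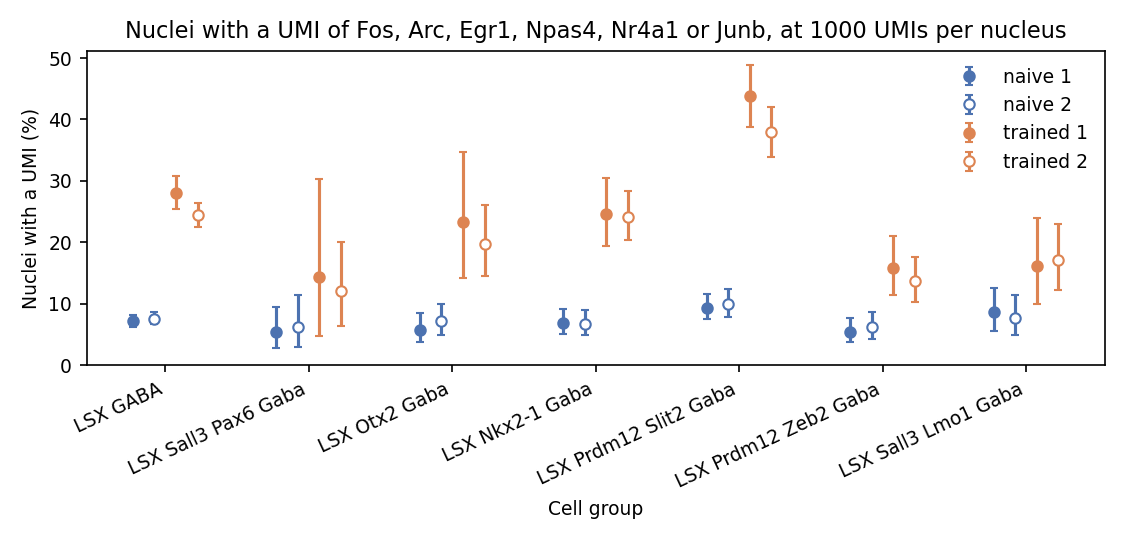
Percent of nuclei (y axis) with a UMI of Fos, Arc, Egr1, Npas4, Nr4a1 or Junb after every nucleus was thinned to 1000 UMIs, in LSX GABA and its subclasses, with 1 point per library and bars for exact 95% binomial intervals. Trained libraries averaged 26.2% and naive libraries 7.39% in LSX GABA, and 40.8% and 9.63% in Slit2.

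The make-up of the libraries by mapped class differed as well. The LSX GABA share of nuclei was 34.2% ± 1.07 in trained and 42.1% ± 0.677 in naive libraries (0.813-fold, edgeR adjusted p = 0.0449). At the same adjusted p by edgeR, 4 of 12 classes tested rose: IT-ET Glut (95.2-fold), OB-IMN GABA (22.7-fold), MB GABA (13.8-fold) and HY GABA (9.17-fold). Of 24 subclasses, LSX Otx2 fell (0.567-fold, 6.32% to 3.57% of nuclei, edgeR adjusted p = 1.40e-07) and LSX Prdm12 Zeb2 fell (0.821-fold, edgeR adjusted p = 0.0482). Choroid plexus cells, CHOR (5.00-fold), tanycytes (3.74-fold), OB-STR-CTX immature neurons (13.0-fold) and IT AON-TT-DP neurons (31.7-fold) rose. The class changes were 0 in number without naive replicate 1, 0 without naive replicate 2, and 0 of 8 with only nuclei of at least 1000 UMIs. With only those nuclei the log2 changes of LSX GABA (0.56) and LSX Prdm12 Zeb2 (0.71) lay above 0, and 0 of 16 subclasses rose and 4 fell. By clusters 2 of 17 subclasses rose and 3 fell. With the replicate block 7 classes changed, adding a rise of Astro-Epen (log2 0.22, edgeR adjusted p = 0.00322) and a fall of Vascular (-0.44, edgeR adjusted p = 0.0388). IT-ET Glut held 2 and 2 naive against 247 and 90 trained nuclei, with trained median depths of 153 and 204 UMIs. OB-IMN GABA held 3 and 5 against 104 and 53 nuclei, with trained median depths of 316 and 334 UMIs. Trained nuclei of neuronal classes without an expression comparison had median bootstrap probabilities of 0.46 and 0.40, and 61.4% and 56.1% lay in non-neuronal clusters. The rises of such classes are therefore rises of mapped labels, not shown to be of those cell types.

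The authors' deposited differential expression values, from their own model on the Leiden clusters, mostly had the same sign for the genes called here. Of the 1266 genes called in LSX GABA, 1258 (99.4%, exact Clopper-Pearson 95% interval 98.8 to 99.7%) had the same sign there, and 109 were called by the authors in any of the 12 matching clusters. For all neurons 1586 of 1609 (98.6%) had the same sign, for Astro-Epen 326 of 334, for OPC-Oligo 151 of 154, for Immune 55 of 58 and for Vascular 9 of 12. Across all genes tested in LSX GABA the share was 84.6%. Both analyses used nuclei of the same 4 libraries, so shared signs are no independent check. The interval treats genes as independent, which they are not. In the authors' oligodendrocyte cluster their model gave log2 changes of 2.13 for Fos, 1.92 for Junb, 1.45 for Nr4a1 and 1.14 for Egr1. In the OPC-Oligo sums here only some immediate early genes had enough counts to be measured, and none of those passed edgeR. Nr4a1 was measured there, and its trained and naive levels, given above, lay within their spread, unlike its 1.45 in the authors' model. Beyond signs, the authors' values and these sums were not otherwise compared gene by gene.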

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

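What each test weighed here would show was written before its result was seen for gene length, and after for all others. Thinning of each nucleus was itself a setting fixed beforehand, while the grouping of nuclei by Leiden cluster was chosen after the data were seen.

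The first pattern is the rise of immediate early genes in trained LSX GABA nuclei, with a median log2 change of 2.5 over 32 members. Against fewer UMIs per nucleus as its source, the median was 2.42 ± 0.24 (SE) with every nucleus thinned to 1000 UMIs. With nuclei grouped by Leiden cluster it was 2.49, which cannot tell whether nuclei of other types were mapped to the class. Nearly all nuclei mapped to LSX GABA already lay in LSX GABA clusters, with only 1 in cluster 0, 2 in cluster 17 and 1 in cluster 23. For free RNA shared by all droplets, the summed level of the list in oligodendrocyte nuclei was at most 0.988 times the naive mean in a trained library. The same sum rose in LSX GABA nuclei. Only some members had enough counts to be measured in OPC-Oligo nuclei, and a rise of scarcer members could go unseen in the sum. It therefore cannot decide on free RNA, and the authors' own model gave Fos a log2 change of 2.13 in their oligodendrocyte cluster. Tone and shock pairing cannot be told apart from handling, the chamber or the separate processing of each group's pooled punches, since no library comes from another arm and 2 libraries a group allow no exact p below 0.333. A biological response to training is thus among the open explanations, as untested.

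The second pattern is the rise of myelin and glial transcripts in trained nuclei of all neuronal classes, such as Ptgds at 102 CPM against 2.31 CPM. In LSX GABA nuclei the summed oligodendrocyte markers in a trained library were at most 1.39 times the naive mean, against 11.6 times in all neurons. This cannot decide on free RNA shared by all droplets, since such RNA is a smaller share of deeper nuclei. Trained LSX GABA nuclei had median depths of 1097 and 1784 UMIs. Trained nuclei of neuronal classes without a comparison of their own had 216 and 318 UMIs. Oligodendrocyte markers also rose in Immune nuclei, as given above. Glial nuclei mapped to neuronal classes remain a candidate source: grouped by Leiden cluster, the ratio in neurons was 1.24. In trained libraries 4.26% of nuclei had a neuronal class but lay in a non-neuronal cluster, against 0.0816% in naive libraries, and the singlet sort in the protocol would not remove whole glial nuclei. No biological explanation was tested.

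The third pattern is the fall of synaptic adhesion, glutamate receptor and ion channel genes in trained LSX GABA nuclei, with a median log2 change of -0.11 over 95 members. Shifted shares of the lateral septum subclasses are argued against, since the median was below 0 in 6 of 6 subclasses. Gene length may account for it: the median lay at percentile 19.0 of random lists matched on length and mean expression, whose own median was -0.10. In simulated lists of this size, 43 of 50 lowered by 0.1 fell below the 2.5th percentile, against 1 of 50 left unchanged. Log2 changes fell with gene length in other classes too (Spearman rho -0.276 in OPC-Oligo, -0.324 in CNU-HYa Glut and -0.184 in Astro-Epen). The lists called upward were not matched on length. Fewer UMIs per nucleus cannot be told apart from the other explanations, since the median was -0.0426 ± 0.0189 (SE) with every nucleus thinned to 1000 UMIs, within its error of the bounds set for it.

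Other results stood out because a training effect differed between groups of nuclei by an interaction test in edgeR. Between neurons and non-neuronal nuclei this held for 607 genes, among them Ptgds (difference of log2 changes 5.37), Apoe (4.99), Trf (4.32) and Htr2c (-2.61). Between a lateral septum subclass and the other LSX nuclei it held for 98 genes in Slit2, 58 in Zeb2, 23 in Lmo1, 6 in Pax6 and 1 in Otx2. In Slit2 nuclei the log2 changes were higher for Tiparp (1.87), Homer1 (0.97), Zdbf2 (0.93), Ina (1.24) and Sst (0.85). The count of 607 was 272, 215 or 331 without naive replicate 1, naive replicate 2 or trained replicate 1, and 115 by DESeq2, 55 with the sums thinned and 262 by clusters. By clusters Ptgds, Apoe and Trf were no longer among the 5 smallest p, so the glial nuclei weighed for the second pattern remain a candidate source for these genes. Htr2c stayed among the 5 (-2.66). Its non-neuronal level was not separated from the larger share of choroid plexus cells in trained libraries.

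Nuclei of neuronal classes that entered the sum of all neurons but no comparison of a class of its own made up 10.0% of trained library 1 and 3.92% of trained library 2, a signal above the 0.290% and 0.228% of the naive libraries. These 541 and 237 trained nuclei had median depths of 216 and 318 UMIs and median bootstrap probabilities of 0.46 and 0.40, and 61.4% and 56.1% of them lay in non-neuronal clusters.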

How the results depend on the processing

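Most other settings were chosen before the data were examined, while grouping by Leiden cluster and leaving out the 5% of nuclei with the highest doublet scores were chosen after the results were seen. Over 3075 values of the 223 named pairs of gene and group under all alternatives, 2613 kept their direction and their side of the threshold, 454 kept the direction but lost the threshold, and 8 changed sign. With every nucleus thinned to 1000 UMIs, 68 of 143 values kept direction and side, 71 lost the threshold and 4 changed sign. Without naive replicate 2, 85 of 220 lost the threshold. In LSX GABA nuclei, 20 to 30 immediate early genes were called up under every alternative, with a list median between 2.34 and 2.66 and Fos between 3.33 and 4.04 (log2). Counts of genes moved most, and for all counts below the cause was not tested, except that leaving out a library leaves 1 group with a lone sample, assumed to vary like the other group, and that thinning leaves fewer UMIs. The trained depth limits what can be seen: changes of 2-fold were recovered for 63.6% of simulated LSX GABA genes, and small groups such as Vascular, Immune, CNU-LGE GABA, CNU-HYa GABA and Pax6 rest on few UMIs.

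By DESeq2 in place of edgeR, counts were 585 in all neurons (1609 by edgeR), 467 in LSX GABA (1266), 7 in CNU-HYa GABA (18), 13 in CNU-HYa Glut (115) and 115 in Astro-Epen (334). They were 67 in OPC-Oligo (154), 0 in Vascular (12), 22 in Immune (58) and 0 in Pax6 (1). In the other groups they were 20 in Otx2 (33), 72 in Nkx2-1 (163), 245 in Slit2 (828), 35 in Zeb2 (163), 16 in Lmo1 (40) and 115 for the interaction of neurons and non-neuronal nuclei (607). With the replicate number as a block they were 2750 in all neurons, 2141 in LSX GABA, 45 in CNU-HYa GABA, 511 in Astro-Epen, 321 in OPC-Oligo, 40 in Vascular, 9 in Pax6, 51 in Otx2, 401 in Nkx2-1 and 371 in Zeb2. Of the 223 named pairs of gene and group, 2 lost the threshold under the block, Lsamp in Otx2 among them. Zic1 in LSX GABA, 2 lists in all neurons and the shares of Astro-Epen and Vascular passed only with it. Of all genes called without it, the block kept 105 of 115 in CNU-HYa Glut, 796 of 828 in Slit2, 57 of 58 in Immune, 32 of 33 in Otx2, 38 of 40 in Lmo1 and every one in the other groups. With the summed counts thinned to the smallest library they were 945 in all neurons, 783 in LSX GABA, 0 in CNU-LGE GABA, 6 in CNU-HYa GABA, 24 in CNU-HYa Glut, 82 in Astro-Epen and 40 in OPC-Oligo. So thinned, they were 0 in Vascular, 4 in Immune, 1 in Otx2, 86 in Nkx2-1, 383 in Slit2, 17 in Zeb2, 0 in Lmo1 and 55 for the interaction. With every nucleus thinned to 1000 UMIs they were 405 in all neurons and 358 in LSX GABA, and with a bootstrap probability of at least 0.9 they were 846 in all neurons. With no filter on low counts they were 8 in CNU-LGE GABA, 30 in CNU-HYa GABA, 99 in Immune and 107 in Otx2, and with at least 10 CPM in 2 libraries 8 in CNU-LGE GABA, 94 in Immune and 0 in Pax6. Under library size alone they were 5 in Pax6 and 60 in Otx2, and the median log2 change of all genes moved most in CNU-HYa GABA, from -0.02 to 0.05.

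With nuclei grouped by Leiden cluster, counts were 0 in CNU-LGE GABA, 219 in Astro-Epen, 242 in OPC-Oligo, 28 in Vascular, 3 in Immune, 0 in Pax6, 73 in Otx2, 305 in Nkx2-1 and 262 for the interaction, which was 272 with oligodendrocytes as the only non-neuronal nuclei. CNU-HYa GABA had no such value, since it is the majority class of no cluster. Without 1 library at a time, counts ran from 488 to 1426 in all neurons, 429 to 1253 in LSX GABA, 1 to 16 in CNU-LGE GABA, 8 to 39 in CNU-HYa GABA and 8 to 88 in CNU-HYa Glut. They ran from 187 to 308 in Astro-Epen, 60 to 146 in OPC-Oligo, 0 to 38 in Vascular and 19 to 46 in Immune. In subclasses they ran from 1 to 4 in Pax6, 0 to 87 in Otx2, 302 to 607 in Slit2, 52 to 208 in Zeb2 and 12 to 77 in Lmo1, and for the interaction from 215 to 467. The lowest counts of LSX GABA, all neurons and the interaction came without naive replicate 2 (429, 488 and 215).

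Of the 13 lists called in LSX GABA and 15 in all neurons, 0 and 0 were called with an estimated correlation, and 4 and 2 by fry. The microglia list in all neurons had a median log2 change of -0.15 by clusters, against 1.92 by mapped class. Of single genes, those that changed sign in all neurons were C1qa by clusters (-0.68) and, with every nucleus thinned, Cacna1e (0.028), Cntn6 (0.048), Cox4i1 (-0.067) and Gria3 (0.0089). Ano2 in LSX GABA changed sign with a bootstrap probability of at least 0.9 (0.031), and Slc4a10 (0.056) and Slit2 (0.018) in Vascular did so by clusters. For these too the cause was not tested.

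Shares of nuclei that changed numbered 5 of 12 classes, against 8 of 12 with TMM scaling, 3 of 7 by clusters, 0 of 8 with only nuclei of at least 1000 UMIs, and 0 to 7 of 12 without 1 library at a time. With only nuclei of at least 1000 UMIs the log2 changes of 4 groups turned, to 0.56 in LSX GABA, 0.71 in LSX Prdm12 Zeb2, -5.30 in Astro-NT and -7.45 in Astro-TE; by construction this leaves out most glia of the shallower trained libraries. The difference between trained and naive LSX GABA nuclei in the share with an immediate early gene UMI was 18.8 points at 1000 UMIs, 12.4 points at 500 UMIs and 1.40 points unthinned, where the naive nuclei keep more UMIs each.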

Other observations

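Choroid plexus and ependymal genes rose together in Astro-Epen nuclei of trained mice: 6 of 9 measured markers passed edgeR upward and none fell. They were Ttr (log2 2.65), the phosphodiesterase Enpp2 (1.90), Kl, which encodes klotho (2.97), the folate receptor Folr1 (2.5), Clic6 (1.42) and Tmem212 (0.84), with edgeR adjusted p from 4.90e-15 for Ttr to 0.048 for Clic6. Prlr, the prolactin receptor, rose there as well (2.07). In the same libraries choroid plexus cells had a 5.00-fold larger share of nuclei and tanycytes a 3.74-fold larger one. These genes were chosen after their values were seen, and no hypothesis was tested for them.

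In Astro-Epen nuclei the glutamate transporter gene Slc1a2 fell (-0.42) and the growth factor receptor Fgfr3 fell (-0.53), while mt-Co2 (0.86) and mt-Co3 (0.76) rose, again chosen after their values were seen.

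Trained libraries had 10.7% of their UMIs outside called nuclei and naive libraries 7.52%, and the mitochondrially encoded share was 0.164% and 0.106%. The mean number of peak counts per called nucleus was 15830 in naive and 14125 in trained libraries, against means of 4028 and 934 UMIs. Bootstrap probabilities of at least 0.9 were given to 37.2% of trained and 87.9% of naive nuclei, and the mapped class differed from the majority class of the cluster for 10.1% and 1.73% of nuclei.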
